A study of Mus musculus with 15 samples.

How the data were processed

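Gene expression was measured on Affymetrix Mouse Genome 430 2.0 arrays in 5 mouse embryonic stem cell lines, with 3 arrays per line and 15 arrays in all. The deposited values are log2 intensities, 1 per probe set and array, for 45101 probe sets. The labels name RMA and the affy package as the authors' tools, without versions or settings. The log2 scale was inferred from the values, which run from 1.99 to 13.96, since the labels do not state the log base. Scanner files, detection calls and a genome sequence were not used here.

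Each probe set was joined to a gene through the array annotation. Of the probe sets, 34945 carried 1 gene symbol, 932 carried several, 9160 carried none and 64 were controls. A reference gene table of the GRCm38.p6 assembly supplied current symbols, chromosomes and gene order. A gene was represented by the probe set with the highest mean over the 15 arrays among those with 1 symbol, which gave 18193 genes. A gene was tested when it reached 3.864, the median of all values, on at least 3 arrays. This filter kept 12813 genes and removed 5380. No value was missing, and no further normalisation was applied.

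The 5 comparisons between lines were contrasts in a single limma fit (limma 3.58.1, R 4.3.3) over all 15 arrays with a mean for each line and empirical Bayes moderation. The comparison of the 3 parthenogenetic with the 2 fertilised lines was a limma fit on the 5 line means, because the line is the replicate of the mode of origin. P values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05 with at least a 2-fold difference. Standard errors of differences are those of the fit, and SD is the spread between the 3 arrays of a line. Where the mean of a line lay below the filter value of 3.864, the fold is given as a lower bound, computed against that value. Genes are ranked by the fitted difference, which for such genes is not a bound.

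Before the data were examined, 20 gene lists were fixed, with 435 entries of which 399 matched a gene on the array. They covered imprinted genes by expressed allele (paternal or maternal), Y-linked genes, naive pluripotency, primed epiblast, 2-cell-like cells, the germ line, DNA methylation machinery, FGF-ERK targets and feedback, primitive endoderm, trophectoderm, mesendoderm, neuroectoderm, fibroblasts as feeder cells, p53 targets, glycolysis, the cell cycle in mitosis, oxidative phosphorylation, MHC class I and antigen presentation, and glutathione and xenobiotic enzymes. The glycolysis list also holds genes that are not glycolytic enzymes, among them Pdk1, Bnip3, Egln3 and Car9. Each list, and the genes of each of 20 chromosomes, was tested with camera from limma at a preset correlation between genes of 0.01. The adjustment ran over the lists, or chromosomes, of a comparison. Each was tested again with camera at an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way and does not set them against other genes. Another 3 lists, on interferon response, epithelial junctions with keratins, and hypoxia-inducible genes, were made after the results were seen.

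The genes named follow a rule fixed before the data were examined. It takes the 8 called genes with the largest rise and the 8 with the largest fall in the comparisons of OpB6D2 and FpB6D2 with NmB6D2, and 5 each way in the other comparisons between lines. Symbols that are clone or predicted-gene names are left out. It adds up to 4 called members per list by size, and any measured member where a list has no call. It also takes the members of both imprinted lists and of the Y-linked list, Xist, Pou5f1, Nanog and Sox2.

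The alternatives tried were other filters, other ways of choosing or averaging probe sets, median centring, quantile normalisation, a fit restricted to the lines compared, other variance models, array weights, a block on the replicate number, and other thresholds. Each array and each line was also left out in turn, and sex-linked genes were left out. The fit was tested on simulated data of 12813 genes. The 5 comparisons between lines recovered 100% of 100 genes changed by 1.5 log2 units and called 0 unchanged genes. The fit on line means recovered 25% of 100 genes changed by 1.5 and 79% of 100 changed by 3, in a single simulated data set with 1 unchanged gene called. For camera, between 0 and 3 of 100 unchanged lists passed an unadjusted p of 0.05 in a comparison. The simulated genes were independent, so this does not give the error rate for lists of correlated genes. The estimated correlation was 0.59 for the fibroblast list in the comparisons between lines. Plots were drawn with matplotlib 3.10.9.

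The number of arrays limits the precision, and each line was grown from a single derivation. The p values of comparisons between lines therefore measure only the spread between arrays of a line, which is not said to include separate cultures. Array titles give a replicate number for 13 arrays and none for 2, 1 each of OpB6D2 and FpB6CBA. Strain variants under probes were not tested, so folds between any of the lines can include differences in probe match. Lines from B6D2F1 oocytes need not share the genotype of NmB6D2 or of each other. H19 and Snurf had only probe sets annotated to several genes and were not analysed here.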

Results

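Expression was profiled in 5 mouse embryonic stem cell lines, with 3 arrays each. NmB6D2 came from embryos of naturally mated C57BL6 females and DBA2 males, and R1, a purchased line, from a cross of the 129S1/SvImJ and 129X1/SvJ substrains. The other 3 lines were parthenogenetic, that is, derived from oocytes activated without sperm, so that both chromosome sets are maternal. OpB6D2 came from ovulated oocytes of B6D2F1 females. FpB6D2 and FpB6CBA came from oocytes grown in cultured follicles of B6D2F1 and B6CBAF1 females. The median log2 expression value of the tested genes lay between 6.634 and 6.79 on the 15 arrays. Across genes, arrays of the same line correlated at 0.994 to 0.998 and arrays of different lines at 0.958 to 0.988, where genes are not independent replicates. The pluripotency factors Pou5f1 (mean 11.38 to 12.02 in the 5 lines), Sox2 (10.96 to 11.26) and Nanog (9.81 to 11.39) were expressed in every line. Xist, the RNA that coats an inactive X chromosome, lay between 4.54 and 4.91.

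The first comparison asked how a parthenogenetic line differed from a fertilised line of the same parent strains. NmB6D2 came from C57BL6 and DBA2 parents and OpB6D2 from oocytes of B6D2F1 females, so their genotypes can differ. Of the 12813 genes tested, 748 (5.84%) were called between OpB6D2 and NmB6D2, 415 higher and 333 lower in OpB6D2. Igf2, a fetal growth factor gene expressed from the paternal allele, was 12.5-fold lower in OpB6D2 (log2 difference -3.64 ± 0.16 SE, adjusted p = 3.6e-10 by limma, 3 arrays per line). The Y-linked translation factor gene Eif2s3y was at least 26.9-fold lower. NmB6D2 expressed this Y-linked gene, so sex and mode of origin differ together between NmB6D2 and the parthenogenetic lines. Of the 8 largest falls, 5 were of genes in the trophectoderm list, 4 of them keratins: Krt7 was 16.9-fold lower (-4.08 ± 0.11), Elf5, a trophoblast transcription factor, at least 8.51-fold lower and Krt18 11.8-fold lower (-3.56 ± 0.10). Cldn7, a tight junction gene, was 12.9-fold lower (-3.69 ± 0.08). The largest rises were Efhc2 on the X chromosome (25.7-fold, 4.69 ± 0.07), Myo1f (17.2-fold, 4.10 ± 0.07), Smtnl1 (11.5-fold, 3.52 ± 0.13) and Dazl, an RNA-binding protein gene of germ cells (9.23-fold, 3.21 ± 0.08). The fold of Efhc2 rests on its weak value of 4.08 in NmB6D2.

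Imprinted genes moved both ways in OpB6D2. Of 23 measured genes with a paternally expressed allele, 7 were higher and 3 lower (10 called when adjusted over the list alone), and the list as a whole did not shift (median 0.25, camera adjusted p = 0.25). The lower genes were Igf2, Sfmbt2 (5.61-fold, -2.49 ± 0.12) and Peg10 (2.48-fold, -1.31 ± 0.27). The higher genes were Plagl1 (4.63-fold), Ndn (4.56-fold, 2.19 ± 0.08), Mest (3.34-fold, 1.74 ± 0.09), Peg3 (2.57-fold, 1.36 ± 0.11), Impact (2.54-fold), Zdbf2 (2.34-fold, 1.22 ± 0.09) and Peg12, which was near background (2.69 in NmB6D2 and 4.03 in OpB6D2, at least 1.12-fold). All 7 were also called higher in R1 than in NmB6D2. Fibroblast markers were higher than in NmB6D2 in both lines as well (7 of 29 in OpB6D2 and 17 of 29 in R1, 0 lower in either). Plagl1 had 0.19 (adjusted p = 0.13) without probe sets that may match several transcripts, and Impact (0.54) and Peg3 (0.78) missed the fold minimum when all probe sets of a gene were averaged. Of 25 genes with a maternally expressed allele, 3 were lower and 1 higher (4 called when adjusted over the list alone; median 0.03, mean -0.16, camera direction down, adjusted p = 0.59). Grb10, a growth inhibitor gene, was 3.43-fold lower (-1.78 ± 0.08), Cdkn1c, a cell cycle inhibitor gene, 3.36-fold lower (-1.75 ± 0.10) and Phlda2 2.73-fold lower (-1.45 ± 0.07), while Mirg was 2.28-fold higher and missed the fold minimum when probe sets were averaged (0.83).

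**Figure D1:**
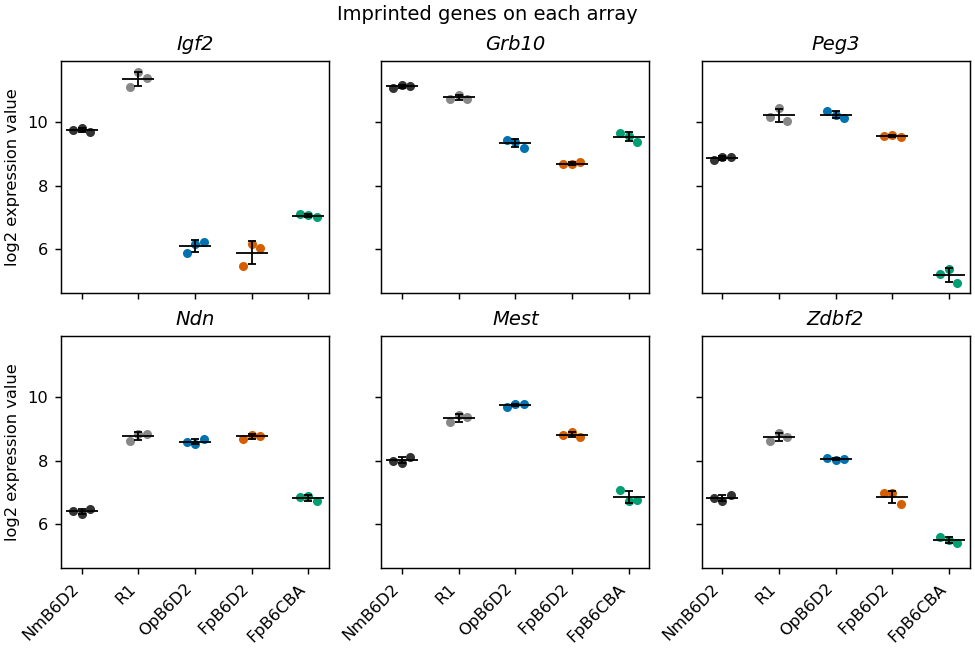
Log2 expression value of 6 imprinted genes on each of the 15 arrays; points are arrays, horizontal ticks are line means and bars are SD (n = 3 arrays). Igf2 and Grb10 are lower in the 3 parthenogenetic lines than in NmB6D2 and R1, while Peg3, Mest and Zdbf2 have their lowest means in FpB6CBA (5.19, 6.86 and 5.51).

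Glycolysis and trophectoderm genes fell as groups in OpB6D2. Of 17 glycolysis genes, 6 fell and 0 rose (6 when adjusted over the list alone; median -0.60, camera adjusted p = 8e-10), led by Aldoc (4.39-fold), Pfkl (2.85-fold), Bnip3 (2.81-fold), a hypoxia-induced mitochondrial gene, and the hexokinase gene Hk1 (2.49-fold). Of 17 trophectoderm genes, 8 fell and 0 rose (8 when adjusted over the list alone; median -0.55, adjusted p = 9.2e-07). The keratins Krt7, Krt8, Krt18 and Krt19, which other epithelia also express, were 4 of the 8, and without them the median was -0.37 (4 of 13 lower, adjusted p = 0.0017). The lineage factors Cdx2 (-0.37), Eomes (-0.37) and Gata3 (-0.22) were not called. In the fertilised R1 against NmB6D2, 6 of the 17 trophectoderm genes were lower and 1 higher (median -0.425, camera adjusted p = 0.052). Elf5 was at least 8.51-fold lower there too. FpB6CBA against NmB6D2 had 2 lower and 0 higher (median -0.288), so high values of these genes in NmB6D2 stay open. Naive pluripotency genes shifted up, with 5 of 30 higher (5 when adjusted over the list alone), among them Tbx3 (5.90-fold), Prdm14 (5.63-fold), Tcl1 (5.01-fold) and Klf4 (2.59-fold). The list had a camera adjusted p of 0.00016, and an adjusted p = 0.15 with an estimated correlation. In the fertilised R1 against NmB6D2, 7 of this list were higher and 4 lower (median 0.33, camera adjusted p = 0.058). Tbx3 (2.93 log2 units), Prdm14 (1.74), Tcl1 (3.51) and Klf4 (1.2) were higher there too, so low values in NmB6D2 stay open. Of 22 germ line genes, 7 were higher and 2 lower (adjusted p = 0.025, and adjusted p = 0.24 with an estimated correlation). Fibroblast markers were also higher, 7 of 29 with a median of 0.73 (adjusted p = 2.8e-06, and adjusted p = 0.39 with an estimated correlation), including Ccl2 (5.68-fold), a chemokine gene.

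Smaller shifts in OpB6D2 were those of p53 targets (median 0.34, 1 of 19 higher, adjusted p = 0.0071) and of mitotic genes (median -0.25, 0 of 19 called, adjusted p = 0.00078). Y-linked genes had a median of -0.80 and a mean of -1.74 (1 of 4 lower, adjusted p = 0.012). With an estimated correlation the camera adjusted p was 0.24 for p53 targets, 0.3 for mitotic genes and 0.16 for Y-linked genes. The other 10 lists did not pass: neuroectoderm came nearest (3 of 12 higher, adjusted p = 0.051), and oxidative phosphorylation (median 0.06, 0 of 21 called, adjusted p = 0.16) and glutathione and xenobiotic enzymes (median -0.02, 1 higher and 1 lower of 19, adjusted p = 0.88) were among the rest. Without X- and Y-linked genes, neuroectoderm passed camera (adjusted p = 0.037, and adjusted p = 0.21 with an estimated correlation). The 2-cell-like list had 2 measured genes, of which Usp17la was 2.47-fold higher. Median and camera direction differed in sign for MHC class I (median -0.18, adjusted p = 0.94) and glutathione and xenobiotic enzymes, and the median and mean for DNA methylation machinery.

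The X chromosome stood apart. Of 414 X-linked genes, 74 were called higher and 16 lower in OpB6D2, with a median of 0.50 (camera adjusted p = 4.5e-16). The medians of the 19 autosomes against NmB6D2 lay between -0.08 and 0.07. In FpB6D2 the X-linked median was 0.44 and the autosomal medians ran from -0.03 to 0.10, whereas the X-linked median was -0.01 in FpB6CBA and 0.04 in R1.

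**Figure D2:**
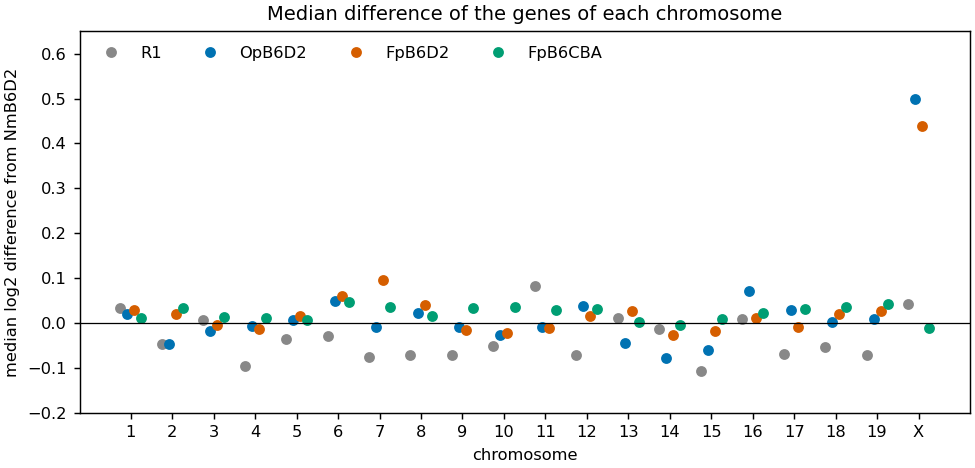
Median log2 difference from NmB6D2 of the tested genes on each chromosome in R1, OpB6D2, FpB6D2 and FpB6CBA; each point is the median over the genes of a chromosome in a line. On the X chromosome OpB6D2 (0.50) and FpB6D2 (0.44) lie above all autosomal medians, and R1 (0.04) and FpB6CBA (-0.01) near 0.

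The second comparison set the parthenogenetic line from follicle-grown oocytes against the same fertilised line. It called 1377 genes (10.7%), 669 higher and 708 lower in FpB6D2. Igf2 was 14.3-fold lower (log2 difference -3.84 ± 0.16 SE, adjusted p = 1.1e-10, 3 arrays per line), Sfmbt2, a paternally expressed Polycomb-related gene, 13.8-fold lower (-3.78 ± 0.12) and Eif2s3y at least 26.9-fold lower. Cldn6 (12.8-fold), Cldn7 (11.9-fold), Elf5 (at least 8.51-fold) and the enolase gene Eno2 (at least 10.3-fold) were also among the largest falls. The largest rises were Efhc2 (59.2-fold, 5.89 ± 0.07), Pramel6 (at least 22.7-fold), Pramel7 (at least 14.7-fold) and Calcoco2 (17.6-fold, 4.14 ± 0.09). The fold of Efhc2 again rests on its weak value of 4.08 in NmB6D2. The 2 comparisons share NmB6D2: 271 genes were higher and 245 lower in both, where independent lists would share 21.7 and 18.4, and 1 was opposite. Across genes, which are not independent replicates, the 2 sets of differences correlated at 0.743, and at 0.213 with separate control lines (OpB6D2 against NmB6D2, FpB6D2 against R1). Simulated arrays that share a control line and have no effect gave 0.499, a value the shared control sets whatever the size of the noise. The covariance was 0.256, against 0.0052 in the simulation, so spread between the NmB6D2 arrays accounts for little of it. Features of NmB6D2 alone enter both comparisons.

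In FpB6D2, maternally expressed genes shifted down: 7 of 25 were lower and 0 higher (7 when adjusted over the list alone; median -0.11, adjusted p = 0.042, and adjusted p = 0.44 with an estimated correlation). Without X- and Y-linked genes the list lost its camera call (adjusted p = 0.058). Grb10 was 5.36-fold lower (-2.42 ± 0.08) and Phlda2 3.28-fold lower (-1.71 ± 0.07). Meg3 (2.98-fold) and Rian (2.56-fold), noncoding RNAs of a shared chromosome 12 cluster, were also lower, but missed the fold minimum when probe sets were averaged (-0.79 and -0.83). Of 23 paternally expressed genes, 3 were higher and 3 lower (6 when adjusted over the list alone; median 0.32, mean -0.04, camera direction up, adjusted p = 0.46). Ndn was 5.09-fold higher (2.35 ± 0.08), and Nnat was 4.87-fold lower (-2.28 ± 0.15). The rise of Plagl1 (5.59-fold) was 0.04 (adjusted p = 0.73) without probe sets that may match several transcripts.

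Glycolysis genes fell in FpB6D2, 7 of 17 with 0 higher (7 when adjusted over the list alone; median -0.74, camera adjusted p = 4.3e-09). Pdk1, a kinase that limits pyruvate oxidation, was 5.76-fold lower (-2.53 ± 0.05), Bnip3 4.83-fold lower and Egln3, an oxygen sensor gene, 4.75-fold lower. Of the glycolytic enzyme genes, Aldoc (-1.98), Pfkl (-1.63) and Hk1 (-1.61) fell as well, while Ldha (-0.65), Aldoa (-0.46) and Pgk1 (-0.33) stayed within the fold minimum. Among naive pluripotency genes 7 of 30 were higher and 2 lower (median 0.44, adjusted p = 0.007, and adjusted p = 0.22 with an estimated correlation). Tcl1 was higher by 3.81 ± 0.07 log2 units, Tbx3 11.5-fold higher and Prdm14 5.00-fold higher, while Lin28a was 6.91-fold lower (-2.79 ± 0.10). Tcl1 (3.51 log2 units), Tbx3 (2.93) and Prdm14 (1.74) were also higher in R1 than in NmB6D2. Trophectoderm genes again shifted down (7 lower and 1 higher of 17, adjusted p = 0.03, and adjusted p = 0.22 with an estimated correlation, or 0.39 without the keratins) and fibroblast markers up (6 of 29 higher, adjusted p = 0.03, and adjusted p = 0.73 with an estimated correlation). MHC class I genes had a median of -0.54 with 1 of 10 lower (adjusted p = 0.03, and adjusted p = 0.24 with an estimated correlation), and that gene, H2-K1, lay at the fold minimum. Of the Y-linked list 2 of 4 were lower (adjusted p = 0.042, and adjusted p = 0.22 with an estimated correlation); Uty, near background at 4.12 and 3.11 and at least 1.19-fold lower, missed the fold minimum without FpB6D2 replicate 1 (-0.96), FpB6D2 replicate 3 (-0.91) or NmB6D2 replicate 2 (-0.96).

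The lists that did not pass in FpB6D2 held some called genes. The de novo DNA methyltransferase genes Dnmt3b (3.02-fold) and Dnmt3a (2.20-fold) and the demethylation enzyme gene Tet1 (2.45-fold) were lower, in a list with 3 lower and 1 higher of 15 (adjusted p = 0.13). Dusp6, a feedback inhibitor of ERK, was 2.78-fold lower (FGF-ERK list, adjusted p = 0.49). X-linked genes were 101 higher and 14 lower of 414 (adjusted p = 1.2e-09, and adjusted p = 0.061 with an estimated correlation). Median and camera direction differed in sign for mesendoderm (0.02) and for glutathione and xenobiotic enzymes (-0.06). Hybridisation control probe sets were 0.48 log2 units higher on the FpB6D2 than on the NmB6D2 arrays, poly-A controls 0.42 higher and the 3' to 5' difference of actin 0.12 higher. On average the arrays of FpB6D2 and FpB6CBA shared such a shift against those of the other 3 lines. The shift cannot be separated from the line here. Hybridisation controls overlapped, at 9.71 on the lowest array of FpB6D2 and FpB6CBA and 9.73 on the highest array of the other 3 lines.

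The third comparison concerned the source of the oocyte, with both lines parthenogenetic and from B6D2F1 females. Oocytes of such females need not share a genotype, so genotype can differ here too. It called 480 genes (3.75%), 168 higher and 312 lower in FpB6D2 than in OpB6D2. The largest rises were the apolipoprotein gene Apoc2 (12.4-fold, 3.64 ± 0.12), Serpinb6c (9.48-fold, 3.24 ± 0.10), Msc (9.15-fold, 3.19 ± 0.12) and Krtdap (at least 7.32-fold). The largest falls were the kinase gene Hunk (6.63-fold, -2.73 ± 0.09), Lin28a, a regulator of let-7 microRNAs (5.54-fold, -2.47 ± 0.10, adjusted p = 6.5e-10) and the linker histone gene H1f2 (4.62-fold, -2.21 ± 0.07). Of 15 primed epiblast genes 5 were lower and 0 higher (5 when adjusted over the list alone; median -0.65), including Lefty2 (3.09-fold), Lef1 (2.72-fold) and Lefty1 (2.31-fold). The list had an adjusted p of 0.016, and an adjusted p = 0.1 with an estimated correlation. Trophectoderm genes were higher, 5 of 17 with 0 lower (5 when adjusted over the list alone; median 0.47, adjusted p = 0.0023, and adjusted p = 0.1 with an estimated correlation, or 0.063 without the keratins), among them Tead4 (3.47-fold), Krt18 (2.97-fold) and Krt8 (2.81-fold).

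Glycolysis genes had a median of -0.14 in FpB6D2 against OpB6D2 (2 of 17 lower, adjusted p = 0.013, and adjusted p = 0.31 with an estimated correlation). MHC class I genes had a median of -0.30 (1 of 10 lower, adjusted p = 0.015, and adjusted p = 0.31 with an estimated correlation). The other 16 lists did not pass. In the imprinted lists, 4 of 23 paternally expressed genes were lower (4 when adjusted over the list alone; median -0.04, adjusted p = 0.31), as were 3 of 25 maternally expressed genes (3 when adjusted over the list alone; median -0.11, adjusted p = 0.082). Mirg was 2.97-fold lower (-1.57 ± 0.19), and Meg3 and Rian were lower by 1.75 and 1.56 log2 units, or 0.74 and 0.79 when probe sets were averaged, below the fold minimum. Median and mean differed in sign for primitive endoderm (-0.06 and 0.02) and neuroectoderm (0.14 and -0.01). The X-linked median was 0.04 (adjusted p = 0.91), and genes of chromosome 7 had a median of 0.12 (adjusted p = 0.013, and adjusted p = 0.19 with an estimated correlation). Hybridisation controls were 0.51 log2 units higher on the FpB6D2 arrays, poly-A controls 0.26 higher and the 3' to 5' difference of actin 0.10 higher. With all probe sets of a gene averaged the count of called genes was 299.

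The fourth comparison concerned the cross, with both lines parthenogenetic and from follicle-grown oocytes. It called 1430 genes (11.2%), 772 higher and 658 lower in FpB6CBA than in FpB6D2. Baiap2l1, an actin regulator gene, was 91.8-fold higher in FpB6CBA (log2 difference 6.52 ± 0.12 SE, adjusted p = 1.4e-13, 3 arrays per line), followed by Ipp (22.1-fold, 4.47 ± 0.08), the lipase gene Liph (21.2-fold, 4.41 ± 0.09) and Cyp2s1 (13.2-fold, 3.73 ± 0.10). Pramel6 was at least 22.7-fold lower, Pramel7 at least 14.7-fold lower and the paternally expressed zinc finger gene Peg3 20.8-fold lower (-4.38 ± 0.11). Pdxdc1 was 28.4-fold lower on its highest probe set, but another of its probe sets differed the opposite way by at least 2-fold, and their mean was -0.12 (adjusted p = 0.15). FpB6D2 enters this comparison and the second with opposite sign, so FpB6CBA was also set against NmB6D2, where 329 genes were higher and 209 lower.

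Genes of primitive endoderm, the extraembryonic lineage beside the epiblast, were higher in FpB6CBA: 16 of 25 rose and 2 fell (18 when adjusted over the list alone; median 1.56, camera adjusted p = 3.9e-05, and adjusted p = 0.18 with an estimated correlation). Cubn was 7.88-fold higher (2.98 ± 0.26), Srgn 7.21-fold higher, Dab2 7.09-fold higher and the laminin gene Lama1 6.18-fold higher. Against NmB6D2, 15 of the list were higher in FpB6CBA and 0 lower, with a median of 1.18. Fibroblast markers had a median of 0.60 in FpB6CBA against NmB6D2 (3 of 29 higher, 0 lower). Against FpB6D2 their median was 0.05 (1 higher, 1 lower). Naive pluripotency genes went the other way, 6 of 30 lower and 1 higher (7 when adjusted over the list alone; median -0.66, adjusted p = 6.6e-05, and adjusted p = 0.17 with an estimated correlation), but against NmB6D2 3 were higher in FpB6CBA and 2 lower, with a median of -0.10. Nr0b1 was 5.66-fold lower, Tbx3 4.92-fold lower, Klf4 3.87-fold lower and Nanog 3.01-fold lower (-1.59 ± 0.06). Of 17 FGF-ERK genes 5 were lower and 2 higher (7 when adjusted over the list alone; median -0.54, adjusted p = 0.013, and adjusted p = 0.18 with an estimated correlation), with Myc 5.40-fold and Spry4 4.80-fold lower and Fos 8.21-fold higher.

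**Figure D3:**
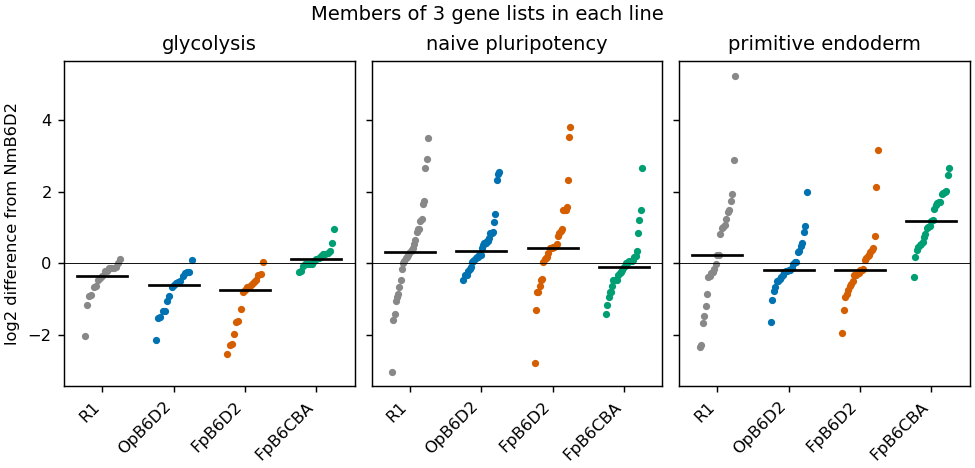
Log2 difference from NmB6D2 of each measured member of the glycolysis, naive pluripotency and primitive endoderm lists in 4 lines; points are genes and horizontal bars are list medians. The primitive endoderm median is 1.18 in FpB6CBA, and the glycolysis median is -0.60 in OpB6D2, -0.74 in FpB6D2 and 0.13 in FpB6CBA.

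Glycolysis genes were higher in FpB6CBA than in FpB6D2, 8 of 17 with 0 lower (8 when adjusted over the list alone; median 0.84, adjusted p = 1e-09). Aldoc was 7.61-fold higher (2.93 ± 0.07), Pdk1 5.67-fold higher and Bnip3 4.81-fold higher. Against NmB6D2 the same list had 0 calls in FpB6CBA and a median of 0.13. Germ line genes were higher, 8 of 22 with 1 lower (9 when adjusted over the list alone; median 0.67, adjusted p = 0.0018, and adjusted p = 0.18 with an estimated correlation), including Asz1 (8.19-fold) and Mov10l1 (4.14-fold), both of the pathway that silences transposons in germ cells. Of 10 MHC class I genes 3 were higher (3 when adjusted over the list alone; median 0.93, adjusted p = 0.0026, and adjusted p = 0.18 with an estimated correlation). They were H2-K1 (2.44-fold), Psmb9 (2.28-fold) and H2-D1 (2.57-fold), the last at 0.16 (adjusted p = 0.26) without probe sets that may match several transcripts. Against NmB6D2, 1 of the 10 was higher in FpB6CBA and 0 lower, with a median of 0.28.

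Among imprinted genes in FpB6CBA, 6 of 23 paternally expressed genes were lower and 4 higher (10 when adjusted over the list alone; median -0.20, adjusted p = 0.25). Besides Peg3, Mest was 3.90-fold lower (-1.96 ± 0.09) and Ndn 3.82-fold lower (-1.93 ± 0.08), while Sfmbt2 was 4.39-fold higher (2.13 ± 0.12). Of 25 maternally expressed genes 5 were higher and 0 lower (5 when adjusted over the list alone; median 0.21, adjusted p = 0.079), with Ascl2 4.47-fold, Cdkn1c 4.26-fold and Phlda2 3.01-fold higher. Zfp57, which encodes a zinc finger protein that protects imprints, was 5.11-fold lower (-2.35 ± 0.15), in a DNA methylation list that did not shift (adjusted p = 0.97). X-linked genes were lower, 78 of 414 with 12 higher (median -0.47, adjusted p = 2.4e-12). The other lists did not pass, and median and camera direction differed in sign for mesendoderm (-0.02) and DNA methylation machinery (0.02), and median and mean for primed epiblast (0.06 and -0.05). Poly-A controls were 0.62 log2 units higher on the FpB6CBA arrays, hybridisation controls 0.11 and the 3' to 5' difference of actin 0.07. Replicate 3 of FpB6CBA was the highest array in poly-A controls (9.60) and the lowest of its line in hybridisation controls (9.71, against 10.37 and 10.41). Without that array 1470 genes were called.

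The fifth comparison was between the 2 fertilised lines, which also differ in strain (R1 from 129S1/SvImJ and 129X1/SvJ, NmB6D2 from C57BL6 and DBA2), so it does not isolate differences between lines of the same origin. It called 1651 genes (12.9%), 947 higher and 704 lower in R1 than in NmB6D2. Genes of mesendoderm, the precursor of mesoderm and endoderm, were higher in R1: 7 of 14 rose and 0 fell (7 when adjusted over the list alone; median 1.23, camera adjusted p = 6.6e-05). Mesp1 was 24.5-fold higher (4.62 ± 0.18 SE, 3 arrays per line), Fgf8 at least 9.21-fold higher, Evx1 at least 10.1-fold higher and Mixl1 at least 7.77-fold higher. The largest rises were the apelin receptor gene Aplnr (2.76, near background, in NmB6D2 and 8.99 in R1, adjusted p = 6.3e-15), the interferon-induced Gbp2b (at least 34.1-fold), the retinoic acid hydroxylase gene Cyp26a1 (46.3-fold, 5.53 ± 0.13) and the maternally expressed Asb4 (at least 20.2-fold). The largest falls were Calml4 (38.1-fold, -5.25 ± 0.11), Car4 (at least 24.1-fold) and Rhox6 (at least 25.9-fold); Pdxdc1 was at least 36.1-fold lower on its highest probe set, but -0.29 as the mean of its probe sets.

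Germ line genes were lower in R1, 10 of 22 with 1 higher (11 when adjusted over the list alone; median -0.69, adjusted p = 0.00074, and adjusted p = 0.14 with an estimated correlation), with Rhox5 21.1-fold and Nlrp4f at least 14.2-fold lower. Fibroblast markers were higher, 17 of 29 with 0 lower (17 when adjusted over the list alone; median 1.13, adjusted p = 1.5e-06, and adjusted p = 0.32 with an estimated correlation), with Timp3 6.77-fold and Col5a1 6.60-fold higher. Of 10 MHC class I genes 3 were higher (median 0.77, adjusted p = 0.00074, and adjusted p = 0.14 with an estimated correlation), led by the immunoproteasome gene Psmb8 (8.06-fold). Smaller downward shifts were those of glycolysis (2 of 17 lower, median -0.36, adjusted p = 0.00074, and adjusted p = 0.14 with an estimated correlation) and mitotic genes (1 of 19 lower, median -0.43, adjusted p = 0.00012, and adjusted p = 0.22 with an estimated correlation). The DNA methylation list also shifted down (2 of 15 lower, adjusted p = 0.043, and adjusted p = 0.23 with an estimated correlation). Its called members were Dnmt3a (6.87-fold) and Dnmt3b (4.16-fold).

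Imprinted genes differed between the fertilised lines as well. Of 23 paternally expressed genes, 10 were higher and 4 lower in R1 (14 when adjusted over the list alone; median 0.01, adjusted p = 0.22), from Plagl1 (22.8-fold higher, 4.51 ± 0.12) to Nnat (23.2-fold lower, -4.54 ± 0.15). Igf2 was 3.05-fold higher in R1 (1.61 ± 0.16), or 0.96 when its probe sets were averaged. Of 25 maternally expressed genes, 2 were higher and 1 lower (3 when adjusted over the list alone; median 0.20, adjusted p = 0.08), and Phlda2 was 9.36-fold higher (3.23 ± 0.07). The other lists did not pass, with p53 targets differing in sign between median (-0.06) and camera direction. The X-linked median was 0.04 (adjusted p = 0.67).

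The last comparison, of the 3 parthenogenetic with the 2 fertilised lines, is the one named in the study's title, with the line as the unit. Igf2 had line means of 9.73 in NmB6D2 and 11.34 in R1 against 6.09, 5.89 and 7.06 in OpB6D2, FpB6D2 and FpB6CBA, a difference of -4.19 ± 0.59 (SE, n = 3 and 2 lines). Grb10 had 11.11 and 10.76 against 9.33, 8.69 and 9.53, and Eif2s3y 8.61 and 7.99 against 3.35, 2.78 and 2.73. Both fertilised lines thus expressed a Y-linked gene, so sex goes with the mode of origin. Sex and origin cannot be told apart in this comparison, for X- and Y-linked genes above all. Limma on the 5 line means called 0 genes, with 606 at an unadjusted p under 0.05 where chance gives 641, and the smallest adjusted p was 0.089, that of Eif2s3y. Treating the line as a random block called 56 genes (47 higher, 9 lower), and a fit that ignores the spread between lines called 520. Leaving out NmB6D2 called 66, with the opposite balance (8 higher, 58 lower), and leaving out any 1 of the other 4 lines called 0. On simulated data limma on line means recovered 25% of genes changed by 1.5 log2 units and 79% of those changed by 3. In the deposited data Igf2, at -4.19, had an adjusted p of 0.68 by limma on line means. The 0 calls therefore do not exclude large differences.

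In a count chosen because that test called 0 genes, 39 genes had all 3 parthenogenetic line means at least 1 log2 unit above or below both fertilised line means, 30 higher and 9 lower. With any gap, such an order arises by chance for 20% of unchanged genes, and another split of the 5 lines separated 138 genes. The 39 included 9 X-linked genes and the Y-linked Eif2s3y. Those named here, other than the imprinted genes and Eif2s3y, were picked after their values were seen. Efhc2 (4.55 ± 0.62), Rhox13 (2.89 ± 0.61), a homeobox gene of the testis, and Dazl (2.14 ± 0.55) were higher in the parthenogenetic lines. So were Smtnl1 (2.92 ± 0.61) and Mapt, which encodes the microtubule-binding protein tau (1.83 ± 0.25). Igf2, Grb10 (-1.75 ± 0.31) and Prtg (-2.85 ± 0.39) were lower.

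In this comparison the germ line list had a median of 1.10 (camera adjusted p = 4e-07), mesendoderm -0.69 (adjusted p = 8.8e-05), the Y-linked list -0.81 (adjusted p = 2.7e-05) and the maternally expressed list -0.28 (adjusted p = 0.006), each with 0 members called. Mesendoderm medians against NmB6D2 were -0.01 in OpB6D2, 0.02 in FpB6D2 and 0.08 in FpB6CBA but 1.23 in R1, so R1 alone sets that shift. Germ line medians were 0.51, 0.12 and 0.80 in the same lines and -0.69 in R1. Primed epiblast (-0.57, adjusted p = 0.011), FGF-ERK (-0.30, adjusted p = 0.017), glycolysis (-0.25, adjusted p = 0.017), MHC class I (-0.43, adjusted p = 0.035) and oxidative phosphorylation (0.19, adjusted p = 0.006) also passed. MHC class I medians against NmB6D2 were -0.18 in OpB6D2, -0.54 in FpB6D2 and 0.28 in FpB6CBA, and 0.77 in R1. Glycolysis medians were -0.60, -0.74 and 0.13 in the same lines and -0.36 in R1. In both lists FpB6CBA thus lay above NmB6D2. None of the 20 lists passed with an estimated correlation, where the adjusted p was 0.35 for the Y-linked list, 0.46 for germ line, mesendoderm, maternally expressed, primed epiblast, FGF-ERK and oxidative phosphorylation genes, 0.67 for MHC class I and 0.77 for glycolysis. When adjusted over the list alone, 2 paternally expressed, 1 maternally expressed, 2 Y-linked and 2 fibroblast genes were called. The fibroblast list differed in sign between median (-0.06) and camera direction. The X-linked median was 0.27 (adjusted p = 9.4e-07, and adjusted p = 0.76 with an estimated correlation).

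Camera calls that held with an estimated correlation were glycolysis, trophectoderm and the X chromosome in OpB6D2 against NmB6D2 (adjusted p = 0.011, 0.011 and 0.01), glycolysis in FpB6D2 against NmB6D2 (adjusted p = 0.029), glycolysis and the X chromosome in FpB6CBA against FpB6D2 (adjusted p = 0.023 and 0.027), and mesendoderm in R1 against NmB6D2 (adjusted p = 0.021). Fry passed 18, 17, 16, 14 and 19 of the 20 lists in the 5 comparisons between lines, in the order given, and 1 in the last. In each comparison between lines, as many members of each list were called when adjusted over the list alone as over all genes tested.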

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

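The tests of the array set, of 2 active X chromosomes, of parthenogenetic origin, of feeder RNA, of maternal alleles and of the other probe sets of Ndn with Peg3 and of Impact with Plagl1 were chosen after the result was seen. The hypoxia list was made after the glycolysis shift was seen, but before the values of its own genes were.

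X-linked genes were lower in FpB6CBA than in FpB6D2 (median -0.47), opposite to their shift in FpB6D2 against NmB6D2, and the difference was tested as a contrast. For OpB6D2 against NmB6D2 the values argue against a few strong genes. The 324 X-linked genes not called had a median of 0.398 (95% bootstrap interval 0.346 to 0.472). That interval resamples genes, which are not independent replicates, and holds no spread between arrays or lines. For OpB6D2 and FpB6D2 against NmB6D2 the values argue against a single segment. The lowest median of 4 groups of genes by position on the chromosome was 0.357. Neither test was run on FpB6CBA, so a few genes or a segment are not argued against for its difference from FpB6D2. The array set with higher controls is also argued against, because OpB6D2 and NmB6D2 lie in the same set and differed by 0.498. A hypothesis that the values allow is that OpB6D2 and FpB6D2 may carry 2 active X chromosomes and the other 3 lines 1, since the lowest median of either line against those 3 was 0.359. X chromosome number was not measured, so loss of an X chromosome in FpB6CBA stays open.

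Glycolysis genes were higher in FpB6CBA than in FpB6D2 (median 0.836), opposite to FpB6D2 against NmB6D2, and the difference was tested as a contrast. The array set is argued against as the whole cause, since the list was at -0.601 in OpB6D2 against NmB6D2, which lie in the same set. Parthenogenetic origin is argued against as well, since the list was at 0.131 in FpB6CBA against NmB6D2. A lower hypoxia response in OpB6D2 and FpB6D2 may go with the shift, a hypothesis drawn from these data: hypoxia-inducible genes outside the list had a median of -0.99 in OpB6D2 against NmB6D2. R1 was lower than NmB6D2 too, with medians of -0.355 for glycolysis and -0.495 for these hypoxia-inducible genes. Which of the lines changed cannot be told from these contrasts. Culture density and oxygen are not given in the sources used here, so the cause stays open.

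The paternally expressed genes Impact, Mest, Ndn, Peg12, Peg3, Plagl1 and Zdbf2 were higher in OpB6D2 than in NmB6D2, and Peg3 (5.04), Mest (2.89) and Zdbf2 (2.55) were higher in OpB6D2 than in FpB6CBA, tested as a contrast, having moved opposite ways against NmB6D2. Fibroblast markers moved with the pattern in OpB6D2 against NmB6D2 (median 0.73), and RNA of feeder cells, which the labels do not mention, is argued against as the whole cause for Mest and Peg3: if their whole level in FpB6CBA were feeder RNA, and OpB6D2 held more of it by the largest ratio of any marker (Ccl2, 3.53-fold, where 5 of 29 markers were called higher, 0 lower and the median was -0.03), it would give at most 85.5% of their rise in OpB6D2. This share, 85.5% for Mest and 22.8% for Peg3, assumes feeder RNA of the same make-up in both lines, which was not measured. For Impact, Ndn, Peg12, Plagl1 and Zdbf2 that share was 124% or more, so their levels in FpB6CBA set no limit and feeder RNA cannot be told apart from a change in the lines. A single aberrant probe set is argued against for Ndn and Peg3, whose 6 other expressed probe sets were at 0.71 or more, but not for Plagl1 (0.19) and Impact (0.32), where 100% of the 8 other probe sets being higher says nothing of size, nor for Mest, Peg12 and Zdbf2, which had no other. Expression from maternal alleles without their imprint may apply to some of these genes, but alleles were not measured. Of the 7, 3 were also called higher than in NmB6D2 in FpB6D2 and 1 in FpB6CBA. In the fertilised R1 all 7 were (Peg3 10.21, against 10.23 in OpB6D2), so low values in NmB6D2 stay open as well. Fibroblast markers were higher in R1 too (17 of 29, median 1.13), and the share that feeder RNA could give was not computed for R1.

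Naive pluripotency genes had a median of -0.663 in FpB6CBA against FpB6D2, a tested contrast that is opposite to FpB6D2 against NmB6D2, and MHC class I genes had a median of 0.927 in it, also opposite. FpB6D2 enters both contrasts with opposite signs, and FpB6CBA against NmB6D2 had medians of only -0.10 for the naive genes (3 higher, 2 lower) and 0.28 for MHC class I (1 higher, 0 lower). Hybridisation control probe sets, which the comparisons do not use, were 0.572 log2 units higher on the arrays of FpB6D2 and FpB6CBA than on those of the other 3 lines. Poly-A control probe sets, also unused, were 0.644 higher.

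For each comparison between lines, the 6 arrays can be split 10 ways, too few for a share under 0.05. The real split called 748 genes for OpB6D2 against NmB6D2, 1377 for FpB6D2 against NmB6D2, 480 for FpB6D2 against OpB6D2, 1430 for FpB6CBA against FpB6D2 and 1651 for R1 against NmB6D2. It was the 1 split with as many genes each time, and the highest of the others called 0. The 5 lines also split 10 ways into 3 and 2, too few for a share under 0.05, with 39 separated genes in the real split, as many or more in 3 of the 10, and 138 in the highest other, R1, OpB6D2 and FpB6D2 against NmB6D2 and FpB6CBA. That split has over 3 times the real count and does not follow the origin of the lines; its cause was not tested.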

How the results depend on the processing

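Leaving out X- and Y-linked genes, counting separated genes and leaving keratins out of the trophectoderm list were chosen after the result was seen. Among the lists and genes the naming rule took, no called result turned direction under any setting, but the balance of counts did: FpB6D2 against NmB6D2 had 683 higher and 676 lower after quantile normalisation, 486 and 478 with averaged probe sets and 4012 and 3717 without a fold minimum, where R1 against NmB6D2 had 3973 and 4085. Another probe set of Pdxdc1 differed the opposite way in FpB6CBA against FpB6D2 and in R1 against NmB6D2; other called genes were not followed. Without keratins the trophectoderm list kept its camera call in OpB6D2 against NmB6D2 and lost it in FpB6D2 against NmB6D2 and against OpB6D2. Under other filters, scalings, variance models and weights the counts of called genes stayed within 1.5 times those reported in the 5 comparisons between lines, and limma on line means stayed at 0; without X- and Y-linked genes they were 657, 1260, 450, 1340 and 1574. In these lists of counts the order is OpB6D2 against NmB6D2, FpB6D2 against NmB6D2, FpB6D2 against OpB6D2, FpB6CBA against FpB6D2 and R1 against NmB6D2. Testing every probe set called 1203, 2303, 905, 2265 and 2877, as more features were tested, and dropping the fold minimum called 6370, 7729, 6663, 7725 and 8058. Averaging probe sets called 299 for FpB6D2 against OpB6D2; the cause was not tested. Leaving out each array in turn gave 749 to 775, 1353 to 1383, 469 to 511, 1417 to 1470 and 1640 to 1681, and 0 for parthenogenetic against fertilised lines. An adjusted p under 0.01, a fit on the compared lines alone and a trended robust variance gave the reported counts, since every gene past 2-fold also passed each test. Of 60, 67, 49, 68 and 73 called genes among those the naming rule took, 13, 14, 18, 11 and 11 lost their call under at least 1 setting.

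Parthenogenetic against fertilised lines had 56 called genes with the line as a random block (consensus correlation 0.874), 520 when the spread between lines was ignored, and 66 without NmB6D2 (0 without any 1 of the other 4 lines), where R1 was the 1 fertilised line and is assumed to vary like the others; by construction these rest on fewer lines or on a smaller estimate of spread. Lists passing camera with an estimated correlation were 2, 1, 0, 1 and 1, and 0 on line means; with fry they were 18, 17, 16, 14 and 19, and 1. Lists passing were 10 (FpB6D2 against OpB6D2) and 12 (R1 against NmB6D2) without a filter, 4 (FpB6D2 against NmB6D2) with a filter at the 60th percentile, and 7 (FpB6D2 against OpB6D2) after quantile normalisation; the cause was not tested. The X-linked median of 0.438 in FpB6D2 against NmB6D2 had an adjusted p = 0.061 with an estimated correlation, and that of 0.265 on line means had 0.76, and 0.66 with fry.

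With a replicate block over the 13 numbered arrays the counts were 797, 1388, 574, 1434 and 1688, against 756, 1377, 492, 1437 and 1651 on those arrays without it, and 0 on line means. Replicate numbers did not pair arrays of different lines, as deviations from the line means correlated at -0.181 to 0.127 in 12 pairs. The planned change of the offset added before taking logs did not apply to values already on a log scale. Signal near background limits the genes left out by the filter, which include Kdm5d, Usp9y and Zfy2.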

Other observations

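The 3 lists described here were made after the result was seen, so only counts and medians are given: the tests of the epithelial and interferon lists were chosen after such genes were seen among the largest changes, and the hypoxia list was made from known hypoxia-inducible genes after the glycolysis shift and before the values of its own genes were seen.

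Genes of epithelial junctions and keratins, 4 of which are also in the trophectoderm list, were lower in OpB6D2 and FpB6D2 than in NmB6D2. Of 24 measured genes, 18 fell and 0 rose in each line, with medians of -2.13 and -2.10. In FpB6CBA 18 were higher than in FpB6D2 (median 1.75). R1 had 13 lower and 1 higher than NmB6D2 (median -1.18).

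Hypoxia-inducible genes outside the glycolysis list fell with it. Of 19, 8 were lower in OpB6D2 and 10 in FpB6D2 than in NmB6D2 (median -1.33 in FpB6D2), 11 were higher in FpB6CBA than in FpB6D2 (median 1.45) and 7 were lower in R1 than in NmB6D2 (median -0.50). Interferon response genes differed in R1, where 10 of 18 were higher than in NmB6D2 and 0 lower (median 1.85). The same list had a median of -0.17 in OpB6D2 and -0.05 in FpB6D2 against NmB6D2, with 1 member lower in each and 1 higher in FpB6D2. In FpB6CBA against FpB6D2 it had a median of 0.43, with 2 higher and 1 lower.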
